A study of Drosophila melanogaster with 8 samples.

How the data were processed

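Total RNA of central brains from female pupae was amplified, labelled with Cy3 and hybridised to 8 Agilent arrays, 4 per group, per the labels. The labels give the groups and call the samples biological replicates. Each array's spots were read in 1 channel with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes and the file headers. Per the file headers, the processed intensity of a spot had its background subtracted and was detrended across the array, and low spots carried a surrogate value, with no scaling between arrays. The deposited mean intensity and local background intensity of each spot were used only for an alternative. The authors also deposited a value table, whose log2 scale, per-array centring and lack of per-gene centring were inferred from the values. The median of each of its 8 columns was 7.88, their sorted values differed by at most 0.0061 on average between arrays, as after quantile normalization, and their ranks followed the median spot signal most closely (Spearman correlation 0.995 to 0.998). How that table was made is not given in the sources used here, and it served as an alternative.

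For the main analysis the log2 processed intensity of each spot was reduced by its array's 75th percentile over the 43603 non-control spots. That percentile lay between 437 on control replicate 1 and 915 on knockdown replicate 1. The 1417 control spots and spots with outlier flags (35 to 263 per array, the most on control replicate 3) were left out. Spots were averaged per probe and probes per gene. Of 32162 probes, 19503 were named through a locus tag, 227 through a RefSeq accession and 1123 through a gene name, with the gene table of the current fly assembly (Release 6), and 11309 kept the name in the files. Of 5 probes that the files name DIP2, 4 belong to locus CG7020, and only these were used. Probe positions are those of the files, in the Dm3 build; no annotation of exons was used. A feature, meaning a gene or an unmatched transcript, was tested if it had a probe well above background on all 4 arrays of at least 1 group, which left 15584 features (9960 genes of the gene table and 5624 others) and 21468 probes.

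Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as knockdown minus control, without covariates, at a Benjamini-Hochberg adjusted p of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the 26 lists, each of which had at least 5 measured members. Camera with an estimated correlation and fry were alternatives. On data simulated from the real means and spreads (15547 features, 100 changed per fold size), 34.0% of 1.5-fold and 78.0% of 2-fold changes were recovered, with 10 unchanged features among 122 called. Of 26 simulated lists, the 1 that was shifted by 0.3 was called and 0 others were. The simulated noise was independent between features, and spreads were reassigned at random among them. The simulation therefore does not show how often lists of correlated genes are called without a change.

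The files placed 4 arrays on each of 2 slides, scanned in 2 sessions that follow the slides. Replicates 1 and 2 of both groups were on slide 1 and replicates 3 and 4 on slide 2. On each slide controls held positions 1 and 3 and knockdowns positions 2 and 4, so position on the slide and group cannot be told apart. The scan session as a block is the same fit as the slide as a block.

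The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Named were DIP2, gkt and disco, the 12 genes with the largest change in each direction among those that passed the test without overlap of the groups, and up to 4 members of each list with the smallest unadjusted p. Transcripts with only an accession or clone name were counted and skipped, and 1 gene that the rule names is not reported here. Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the deposited processed values, other filters on dim probes, keeping outlier-flagged spots, the brightest probe per gene, blocks for replicate number and slide, a variance trend with robust moderation, array weights, and leaving out each array in turn.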

Results

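Gene expression was measured in the central brain of female Drosophila melanogaster 24 h after puparium formation (APF), a pupal stage at which the mushroom body is being rebuilt. The mushroom body is a paired brain centre for olfactory memory, whose axons branch into a vertical and a medial lobe. Flies were raised at 29°C. In both groups the neuronal driver elav-Gal4 was combined with UAS-dicer2, which strengthens RNA interference. The knockdown group also carried a hairpin transgene against DIP2 (DISCO interacting protein 2). Each group held 4 biological replicates, and each replicate was hybridised to its own 1-colour array. Of the 43603 non-control spots per array, between 28772 (66.0%) and 33321 (76.4%) were well above background, and 0 were saturated. The number of arrays limits the precision of the comparison. Correlations between arrays over all tested features ran from 0.975 to 0.992.

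The first question was whether the targeted transcript was lower in the knockdown brains. DIP2 (CG7020) fell 1.82-fold, from -0.77 ± 0.17 (SD, n = 4) in controls to -1.64 ± 0.20 (SD, n = 4) in knockdown brains, in log2 units relative to each array's 75th percentile. The change was -0.87 on the log2 scale (SE 0.12, limma adjusted p = 0.0119), and each of the 4 knockdown values lay below each of the 4 control values. The 4 DIP2 probes, on chromosome arm 3L of the Dm3 build, did not move by the same amount. The probe at 250328 to 250387 changed by -0.86 (SE 0.10), the probe at 251720 to 251779 by -1.22 (SE 0.17), the probe at 256237 to 256296 by -0.51 (SE 0.22) and the probe at 256363 to 256422 by -0.88 (SE 0.19). The part of the transcript that the hairpin targets and the exons under these probes were not analysed here. The change was -0.70 within slide 1 and -1.04 within slide 2 (n = 2 per group each, adjusted p = 0.596 and 0.208). With the slide as a block the adjusted p was 0.0237, and on the deposited processed values the change was -0.52 (adjusted p = 0.00364). The call was lost without control replicate 1 (-0.86, adjusted p = 0.0505) and after normexp background correction (-0.89, adjusted p = 0.355). It was also lost with the replicate number as a block (adjusted p = 0.108). Whether replicate numbers pair the arrays is not settled by these data.

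**Figure D1:**
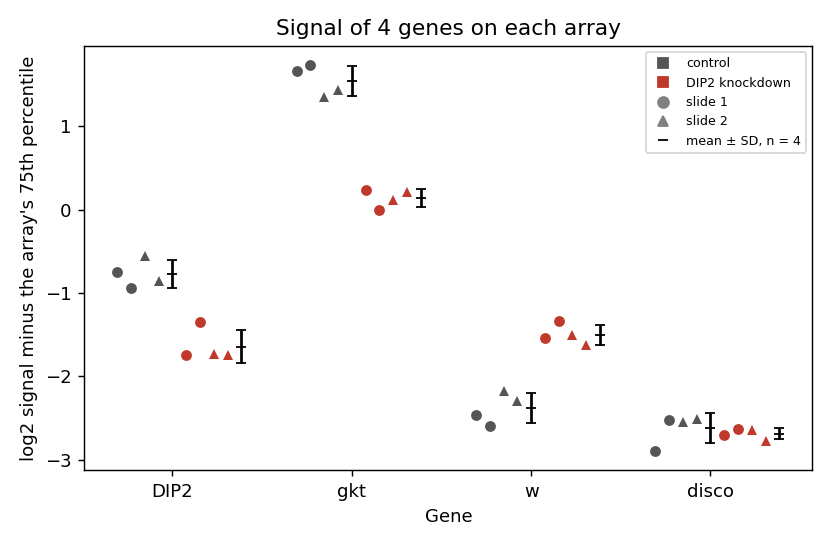
Log2 signal minus the array's 75th percentile (vertical axis) on each array for DIP2, gkt, w and disco (horizontal axis), with controls in grey and DIP2 knockdown in red. Circles are arrays of slide 1 and triangles those of slide 2, and black bars are means ± SD (n = 4). The 4 knockdown values lie below the 4 control values for DIP2 and gkt and above them for w, and the groups overlap for disco.

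The second question, raised by the series title, was how the transcript of glaikit (gkt, CG8825) behaved. The gene encodes the fly tyrosyl-DNA phosphodiesterase. Its signal fell 2.65-fold, from 1.55 ± 0.18 (SD, n = 4) in controls to 0.14 ± 0.11 (SD, n = 4) in knockdown brains, a log2 change of -1.41 (SE 0.11, adjusted p = 9.04e-04). The change exceeded that of DIP2 itself in size. Both gkt probes, on arm 2L of Dm3, moved together, by -1.32 (SE 0.11) at 3162078 to 3162137 and by -1.50 (SE 0.14) at 3162270 to 3162329. Within slides the change was -1.58 on slide 1 and -1.23 on slide 2 (n = 2 per group, adjusted p = 0.260 and 0.138), and with the slide as a block the adjusted p was 0.00189. The noncoding transcript CR31953, picked after its values were seen, has its probe at 3163088 to 3163147 and fell by 1.25 (SE 0.11, adjusted p = 0.00128). In all, 8 other changed loci lay within 500 kb of gkt. The series title presents gkt as found by expression profiling, so its fall here is not counted as independent evidence. After normexp correction the gkt change was -1.17 with an adjusted p of 0.355. The transcription factor gene disco, after which DIP2 is named, changed by -0.07 (SE 0.10, adjusted p = 0.870).

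Across the genome, 306 of 15584 tested features changed in knockdown brains, 144 upwards and 162 downwards. Among named genes well above background on all 8 arrays, Dnaaf3 rose 7.64-fold and CG10936 rose 5.51-fold, while CG11052 was 11.7-fold lower. Among the 306 were 184 genes of the gene table (88 higher, 96 lower) and 122 transcripts known only by an accession or clone name. A 2-fold change or more was seen for 121 features, and the median absolute change was 0.87 on the log2 scale. For all 306 the 4 knockdown values did not overlap the 4 control values. That held for 7.35% of all tested features, against the 2.86% that chance gives.

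Several of the named genes that rose were dim in controls. CheB53a and its neighbour CheB53b, members of a family linked to chemosensation, were not well above background on any control array and rose at least 3.40-fold (adjusted p = 4.31e-04) and at least 1.67-fold (adjusted p = 0.00687). CG9287 rose at least 3.10-fold, CG33654 at least 3.24-fold, the neprilysin-like gene Nepl8 at least 2.87-fold and the cytochrome P450 gene Cyp4ac2 at least 1.76-fold. These bounds set the knockdown mean against the higher of each control array's lowest well-above-background signal and the probe's own signal, and hold for the background-subtracted signal only. The adjusted p values belong to the limma changes and do not test the bounds. On the deposited processed values the log2 rises were 0.24 for CheB53a, 0.22 for CG9287 and 0.15 for Nepl8. There the calls of CheB53b (0.099, adjusted p = 0.355), CG33654 (0.13, adjusted p = 0.0870) and Cyp4ac2 (0.095, adjusted p = 0.221) were lost. The cause of the smaller changes was not tested. The mitochondrial ribosomal protein gene mRpL48 rose by 3.66 on the log2 scale (SE 0.25) and was well above background on 3 of the 4 control arrays, and the bestrophin gene Best2 rose by 1.86 (SE 0.18) and was so on 2. The 2 probes of Dnaaf3, a dynein arm assembly factor gene, rose by 2.76 and 3.11, and SPH93, a serine protease homologue gene, rose 4.75-fold. On the deposited processed values Dnaaf3 rose by 0.95, CG10936 by 1.04, SPH93 by 0.65, mRpL48 by 0.76 and Best2 by 0.19, all called. The SPH93 call was lost without any of control replicates 1 to 3 or knockdown replicates 2 to 4 (adjusted p of up to 0.0928), and the Nepl8 call without control replicate 1 or any of the 4 knockdown replicates (up to 0.0978). With no filter on dim probes both calls were lost (adjusted p = 0.0727 for SPH93 and 0.0704 for Nepl8), and with array weights that of SPH93 (adjusted p = 0.0662). After normexp correction CheB53a, CheB53b, CG9287, CG33654, Nepl8, Cyp4ac2 and Best2 all changed sign, to values between -0.64 for CheB53a and -1.0025 for CheB53b, and none passed the test.

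Among the named genes that fell, the tubulin tyrosine ligase-like gene TTLL15 was lower by at least 9.60-fold (limma adjusted p = 9.04e-04, which does not test the bound), the acyl-CoA oxidase gene Acox57D-d by at least 6.19-fold, the rhomboid gene rho-6 by at least 3.94-fold and the cytochrome P450 gene Cyp4d21 by at least 3.51-fold, with 0 of 4 knockdown arrays well above background for each. On the deposited processed values these changes were -0.41, -0.24, -0.18 and -0.19, and the Cyp4d21 call was lost (adjusted p = 0.2997), so the bounds hold for the background-subtracted signal only. CG11052 fell by 3.54 on the log2 scale (SE 0.16, adjusted p = 7.80e-05) and CG3397 fell by 2.70 (SE 0.10, adjusted p = 2.40e-05) as the mean of 2 unlike probes, at -3.44 and -1.96. The brightest CG3397 probe, the 1 well above background on all 8 arrays, gave -1.96 (adjusted p = 2.20e-04). For CG11052 and CG3397 on the deposited values the changes were -1.10 and -0.86, both called. The methuselah-like gene mthl3 fell by 2.39 and was well above background on 2 of 4 knockdown arrays. CG31955, the cytochrome P450 gene Cyp6a13 and ninaA fell by 2.09, 1.76 and 1.74. On the deposited values mthl3, CG31955, Cyp6a13 and ninaA were at -0.22, -0.73, -1.15 and -0.26, all called. The rho-6 change was -2.0043 with no filter on dim probes. Fdh, a formaldehyde dehydrogenase gene, fell by 2.81 as the mean of 2 probes that disagreed, at -5.38 and -0.24, and was at -0.79 on the deposited values. CG34206 fell by 1.92, and its 2 probes also disagreed, at -3.69 and -0.15. With the brightest probe standing for the gene, the Fdh change was -0.24 (adjusted p = 0.304) and neither Fdh nor CG34206 was called. The CG34206 call was also lost on the deposited values (-0.20, adjusted p = 0.465), with no filter on dim probes (adjusted p = 0.0704) and without any of the 4 control replicates or knockdown replicates 3 and 4 (adjusted p of up to 0.0908).

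The count of 306 fell when single arrays were left out, to 168, 257, 186 and 160 without control replicates 1, 2, 3 and 4, and to 191, 210, 170 and 200 without knockdown replicates 1, 2, 3 and 4. It was 263 with the slide as a block, 0 within slide 1 and 6 within slide 2, where 2 arrays per group were left. After normexp correction 3 features passed.

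Of the 26 gene lists, the axon guidance, planar polarity, mushroom body, ecdysone, neuroblast, pan-neuronal and glial lists held no called gene. Among 62 measured genes of axon guidance and adhesion none passed. The 2 with the smallest p were NetA, a netrin guidance cue (0.30, SE 0.09, adjusted p = 0.241), and trn (-0.28, SE 0.11, adjusted p = 0.406). None of 21 planar polarity and Wnt pathway genes passed, with arr, a Wnt co-receptor, at 0.23 (SE 0.07) and stan, an atypical cadherin gene, at 0.18 (SE 0.09). None of 29 mushroom body genes passed, with ey at -0.23 (SE 0.09) and Imp at 0.16 (SE 0.07). None of 37 genes of the ecdysone response and neuronal remodelling passed, with Eip63E at -0.35 (SE 0.08, adjusted p = 0.0702) and the activin receptor gene put at -0.35 (SE 0.09). None of 26 neuroblast and precursor genes passed, with grh at 0.71 (SE 0.16, adjusted p = 0.0855) and cas at -0.45 (SE 0.16). None of 52 pan-neuronal and synaptic genes passed, with Nlg1 at -0.54 (SE 0.16) and nAChRalpha6 at -0.36 (SE 0.11, 2 probes at -0.68 and -0.043). None of 32 glial genes passed, with the transporter genes Eaat1 at -0.39 (SE 0.11) and Gat at -0.31 (SE 0.10). In all, 17 lists with 591 measured members held no gene that limma called and 0 that an ordinary test with Benjamini-Hochberg adjustment called, while 47 members had an unadjusted p under 0.05. Adjusted over the list alone, 0 of their members passed. The 17 lists were grouped for holding no called gene, so their lack of limma calls was set by the grouping. Over all tested features 306 of 15584 were called, and 9.82% had an unadjusted p under 0.05. In the simulation 34.0% of 1.5-fold changes were recovered, so a gene that did not pass may still have changed. Under other settings, grh was called with quantile normalization (0.75, adjusted p = 0.0494) and median centring (adjusted p = 0.0420), arr with the brightest probe (0.33, adjusted p = 0.0481) and Eip63E over genes of the gene table only (adjusted p = 0.0491). With array weights Imp, Eip63E, put, Nlg1 and nAChRalpha6 were called (adjusted p of up to 0.0476).

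Single members passed in lists of neurosecretory, sensory and defence genes. Of 41 neuropeptide and hormone genes, 1 fell (1 adjusted over the list alone), the insulin-like peptide gene Ilp2, by 1.27 (SE 0.22, adjusted p = 0.0252). The Ilp2 call was lost when any of 6 arrays was left out, namely control replicates 1 to 4 and knockdown replicates 2 and 4, with an adjusted p of up to 0.0886, and with no filter on dim probes (adjusted p = 0.0704). Of 35 optic lobe and eye genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone). The eye pigment transporter gene w rose by 0.88 (SE 0.11, adjusted p = 0.00691) and ninaA, a rhodopsin chaperone gene, fell by 1.74 (SE 0.17, adjusted p = 0.00186), and on the deposited values w was at 0.45 and ninaA at -0.26. Of 44 immune genes, 2 rose and 1 fell (3 and 3 adjusted over the list alone). The antibacterial peptide gene CecA1 rose by 1.35 (SE 0.21), Tep4 rose by 0.76 (SE 0.12) and the attacin gene AttA fell by 0.70 (SE 0.13). The 3 AttA probes ran from -1.69 to -0.18, and its call was lost with the brightest probe (-0.18, adjusted p = 0.757) and on the deposited values (-0.24, adjusted p = 0.252). With no filter on dim probes the AttA and Tep4 calls were lost (adjusted p = 0.0952 and 0.0591). The CecA1 call was lost without any of control replicates 1 and 4 or knockdown replicates 2 and 4 (adjusted p of up to 0.0597), the Tep4 call without any of control replicates 1 and 3 or knockdown replicates 2 to 4 (up to 0.0635) and the AttA call without any array except knockdown replicate 1 (up to 0.110), and CecA1 was at -0.062 after normexp correction and at 0.43 on the deposited values. With array weights Tep4 was at 0.51. Of 20 genes of RNA interference, 2 fell (1 higher and 2 lower adjusted over the list alone), vig by 0.37 (SE 0.07, adjusted p = 0.0372) and the RNA helicase gene Rm62 by 0.42 (SE 0.08, adjusted p = 0.0489). Both calls were lost when any 1 of the 8 arrays was left out, with adjusted p of up to 0.160 and 0.162, and with the slide as a block, median centring, no filter on dim probes or the brightest probe (adjusted p of up to 0.438). The Rm62 call was also lost on the deposited values (-0.28, adjusted p = 0.0729) and with quantile normalization (adjusted p = 0.0744).

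Called members were also found in metabolic and repair lists. Of 97 detoxification genes, 3 rose and 6 fell (4 and 7 adjusted over the list alone). The glutathione S-transferase gene GstE1 rose by 1.35 (SE 0.13, adjusted p = 0.00202) and GstZ2 fell by 0.93 (SE 0.09, adjusted p = 0.00153), beside Cyp4ac2 and Cyp6a13 above. On the deposited values GstE1 was at 0.78. Of 42 genes of DNA ends and repair, 3 fell (2 higher and 4 lower adjusted over the list alone). They were gkt, the alkylguanine-DNA alkyltransferase gene agt, by 1.54 (SE 0.12, adjusted p = 9.80e-04), and the excision repair nuclease gene Ercc1, by 0.52 (SE 0.07, adjusted p = 0.0109). The Ercc1 call was lost with median centring (adjusted p = 0.145), and agt was at -0.38 on the deposited values (adjusted p = 0.00876). Of 55 genes of lipid metabolism, 1 rose and 2 fell (1 and 3 adjusted over the list alone). Acox57D-d and Agpat2 fell, the latter by 0.52 (SE 0.08, adjusted p = 0.0193). The 1 that rose, Fancl, is a Fanconi anaemia ubiquitin ligase gene and not a lipid enzyme, at 0.72 (SE 0.14, adjusted p = 0.0422). The Fancl call was lost when any 1 of the 8 arrays was left out (adjusted p of up to 0.138), and the Agpat2 call without any of control replicates 1 and 4 or knockdown replicates 1, 3 and 4 (up to 0.0832). With no filter on dim probes both were lost (adjusted p = 0.116 and 0.0704), as was Fancl on the deposited values (0.21, adjusted p = 0.0957) and Agpat2 with median centring (adjusted p = 0.141). Of 79 genes of mitochondrial respiration, 1 rose (1 adjusted over the list alone), COX4, at 0.60 (SE 0.10, adjusted p = 0.0206). Its brightest probe alone gave -0.058, and its call was lost without any of replicates 1, 3 and 4 of either group (adjusted p of up to 0.0868), with median centring (adjusted p = 0.109) and with no filter on dim probes (adjusted p = 0.0704).

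Tested as wholes with camera, 5 lists passed at the preset correlation of 0.01, and 0 of them passed with an estimated correlation. The cytoplasmic ribosomal protein genes lay lower in knockdown brains, with 80 of 91 below control, no member called and a median of -0.16 (adjusted p = 5.59e-06, and adjusted p = 0.905 with an estimated correlation). That median was -0.11 within slide 1, -0.19 within slide 2 and -0.11 without control replicate 1. It was -0.012 after quantile normalization (adjusted p = 0.788) and -0.0082 on the deposited values (adjusted p = 0.799). After normexp correction the median had the opposite sign, 0.074, and the list passed there (adjusted p = 5.85e-07). Mitochondrial respiration genes had a median of -0.10, with 61 of 79 below control (adjusted p = 0.0215, and adjusted p = 0.903 with an estimated correlation). Its median was -0.15 within slide 1, -0.03 within slide 2 (adjusted p = 0.999) and -0.05 after quantile normalization (adjusted p = 0.346). After normexp correction the respiration median had the opposite sign, 0.11, and the list passed there (adjusted p = 1.55e-07). The respiration call was lost without control replicates 1 (-0.067, adjusted p = 0.113) and 2 (-0.11, adjusted p = 0.0729) and knockdown replicate 2 (-0.10, adjusted p = 0.181). It was also lost on the deposited values (-0.035, adjusted p = 0.221), with median centring (-0.056, adjusted p = 0.117), with array weights (-0.072, adjusted p = 0.108) and with no filter on dim probes (-0.11, adjusted p = 0.138). Cell cycle genes had a median of 0.05, with 41 of 55 above control (adjusted p = 0.0220, and adjusted p = 0.903 with an estimated correlation), at 0.06 within slide 1 (adjusted p = 0.214), 0.08 within slide 2 (adjusted p = 0.0562), 0.084 without knockdown replicate 1, 0.099 with median centring and -0.34 after normexp correction. The cell cycle call was lost without control replicate 3 (0.044, adjusted p = 0.0873) and knockdown replicates 2 (0.046, adjusted p = 0.108) and 4 (0.027, adjusted p = 0.0991), and with array weights (0.0089, adjusted p = 0.665). Cell cycle genes with the smallest p were twe at -0.33 and aurA at 0.32. Cuticle and epidermis genes had a median of 0.19, with 35 of 50 above control (adjusted p = 0.0215, and adjusted p = 0.903 with an estimated correlation), at 0.07 within slide 1 (adjusted p = 0.776), 0.29 within slide 2, -0.81 after normexp correction and -0.076 with no filter on dim probes. The cuticle call was lost without control replicates 1 (0.028, adjusted p = 0.521) and 3 (0.14, adjusted p = 0.0700) and knockdown replicates 3 (0.089, adjusted p = 0.395) and 4 (0.11, adjusted p = 0.0569), and with array weights (-0.069, adjusted p = 0.678). The median was 0.33 without knockdown replicate 1, 0.036 on the deposited values and 0.11 over probes well above background on all 8 arrays. Its members with the smallest p were the cuticle protein genes Cpr57A, at 0.51 as the mean of 2 probes of opposite sign (-0.24 and 1.26) and called with the brighter of them (adjusted p = 2.20e-04) and on the deposited values (0.44, adjusted p = 9.57e-04), and Cpr49Ag at 0.49. The list of DIP2 and named partners held 5 genes of which 2, DIP2 and gkt, fell (2 adjusted over the list alone). It holds the targeted gene and the gene of the series title, so its call is not counted as independent evidence. Its median was -0.07, the value of disco, and so does not show the falls of DIP2 and gkt. The camera adjusted p was 0.0238, and 0.718 with an estimated correlation. The median was -0.09 within slide 1 and -0.18 within slide 2, where the call was lost (adjusted p = 0.388). The call was also lost without control replicate 2 (-0.036, adjusted p = 0.198) and knockdown replicate 2 (-0.089, adjusted p = 0.108), and after normexp correction (-0.64, adjusted p = 0.105). The median was -0.16, -0.044 and -0.034 without control replicates 1, 3 and 4. It was -0.14 with array weights, -0.032 with quantile normalization, -0.021 with median centring, -0.019 on the deposited values and 0.00035 with the brightest probe. Fry, which asks whether the genes of a list move one way on balance, called this 1 list (adjusted p = 0.00141). For 6 of the 26 lists the direction given by camera was opposite to the sign of the median.

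Fat body, muscle, gland, tracheal and haemocyte markers, of tissues that can adhere to a dissected brain, had no called member, but several of these lists lay mostly to 1 side. The medians were -0.21 over 19 fat body genes, 0.21 over 29 muscle genes, -0.46 over 12 salivary gland and ring gland genes, 0.06 over 12 tracheal genes and -0.0048 over 23 haemocyte and basement membrane genes, with camera adjusted p of 0.107, 0.107, 0.107, 0.155 and 0.413. Of these, 17 of 19 fat body genes and 11 of 12 gland genes lay below control, 27 of 29 muscle genes and 9 of 12 tracheal genes lay above, and haemocyte genes split 12 to 11. The calls and medians depended on the settings and on single arrays. With all 8 arrays kept, fat body was called with median centring (adjusted p = 0.0265) and the replicate block (adjusted p = 0.0180). The gland list was called with median centring (adjusted p = 0.0208), no filter on dim probes (0.0230), array weights (-0.75, 0.0260) and the replicate block (0.0463). The replicate block also called muscle (adjusted p = 0.00162) and trachea (adjusted p = 0.0180). Muscle turned to -0.22 without knockdown replicate 3 (adjusted p = 0.433), was at 0.019, 0.068 and 0.12 without control replicates 1, 2 and 4, and was called without knockdown replicate 1 (0.45, adjusted p = 5.70e-04) and control replicate 3 (0.44, adjusted p = 0.00124) and within slide 2 (0.37, adjusted p = 0.0451). Fat body was called without knockdown replicate 3 (-0.30, adjusted p = 0.00331) and within slide 1 (-0.16, adjusted p = 0.0201), and was at -0.070 without knockdown replicate 1. The gland list was called without control replicate 3 (-0.66, adjusted p = 0.0483) and knockdown replicate 3 (-0.41, adjusted p = 0.0277) and within slide 1 (-0.66, adjusted p = 0.00201), but stood at -0.10 without knockdown replicate 2 and -0.088 within slide 2. The tracheal list was called without control replicate 4 (0.12, adjusted p = 0.0371) and within slide 1 (0.31, adjusted p = 0.0174), and was at -0.089 within slide 2. After normexp correction muscle was at -0.098, trachea at -0.63 and haemocyte and basement membrane genes at -0.11 (adjusted p = 0.0467). On the deposited values fat body was at -0.10, muscle at 0.12, glands at -0.11 and trachea at 0.038, none called. The members with the smallest p were FASN1 (-0.34) and Yp2 (-0.74) for fat body and how (0.23) for muscle. For glands they were Eig71Ea (-1.69) and spok (-0.86, called without control replicate 2 at -1.12, adjusted p = 0.0398). For trachea they were pio (0.74) and btl (0.52), and for basement membrane LanB1 (0.33). Eye and optic lobe tissue borders the central brain, and its list had a median of -0.05, with 22 of 35 genes below control and 13 above (camera adjusted p = 0.552). Over this list the median was -0.14 within slide 1 (adjusted p = 0.0278) and -0.01 within slide 2 (adjusted p = 0.783). It was -0.12, -0.082 and -0.011 without knockdown replicate 3, control replicate 1 and knockdown replicate 1, with no call, and -0.63 after normexp correction, where the list was called (adjusted p = 0.0172). On the deposited values the list median was -0.0081. Of its photoreceptor genes ninaA was called lower, and inaC was at -1.03 (SE 0.26, adjusted p = 0.121) and called with array weights (adjusted p = 0.00640). The values of others moved when knockdown replicate 3 was left out. ninaE was at 0.68 (SE 1.11), Arr2 at 0.78 (SE 1.08) and Rh6 at 0.38 (SE 0.31), but at -0.41, -0.31 and 0.057 without knockdown replicate 3. ninaC was at -0.57 (SE 0.36) and chp at -0.26 (SE 0.31), and without that array at -0.94 and -0.58, none of these 5 called in either fit. Outside the list and picked after their values were seen, the photoreceptor genes Pph13 and Xport-A fell by 1.04 (adjusted p = 0.0167) and 0.52 (adjusted p = 0.0461). On the deposited values they were at -0.14 (adjusted p = 0.109) and -0.11 (adjusted p = 0.158), and neither was called. Both calls were also lost with no filter on dim probes (adjusted p = 0.0517 and 0.139). The Xport-A call was lost when any 1 of the 8 arrays was left out (up to 0.163), and the Pph13 call without any of control replicates 1, 3 and 4 or knockdown replicates 3 and 4 (up to 0.0607). Of 28 heat shock and stress genes none passed, with a median of -0.11 (-0.046 without knockdown replicate 4, -0.037 within slide 1, -0.019 on the deposited values) and Hsp70Ba at -0.46 (adjusted p = 0.163). Of 13 sex-biased transcripts none passed, with 7 below control, 6 above and a median of -0.05 (camera adjusted p = 0.670). Among them 3 had an unadjusted p under 0.05, and the largest change was 2.33 in size. The noncoding transcript lncRNA:roX1 is part of the male dosage compensation machinery. Its mean was -0.25 ± 0.68 (SD, n = 4) in controls and -2.13 ± 1.59 (SD, n = 4) in knockdown brains (adjusted p = 0.429). The 4 lncRNA:roX1 probes ran from -1.98 to -1.78. Although the labels call the brains female, lncRNA:roX1 was well above background on all 4 arrays of each group. Whether the groups differed in male tissue was not tested.

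The last comparison asked whether changed genes were concentrated on chromosome 3, where the written genotype places the hairpin and which holds DIP2. On chromosome 3, 125 of 6651 tested features changed, against 167 of 8553 on the other chromosomes (odds ratio 0.96, 95% interval 0.75 to 1.22, Fisher's exact test, 2-sided p = 0.766). Against chromosome 2 alone, a test chosen after the result was seen, the odds ratio for chromosome 3 was 0.70 (95% interval 0.55 to 0.90, Fisher's exact test, p = 0.00455). The shares were 2.65% on chromosome 2 (147 of 5546), 1.88% on chromosome 3, 2.13% on chromosome 4 (6 of 282) and 0.514% on the X chromosome (14 of 2725). Changed genes on the X included w. By the same exact test, the odds ratio for chromosome 3 passed the threshold on the deposited processed values (0.77, p = 0.0483) and with array weights (0.84, p = 0.0205). The exact test treats features as independent, although they share the same arrays.

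**Figure D2:**
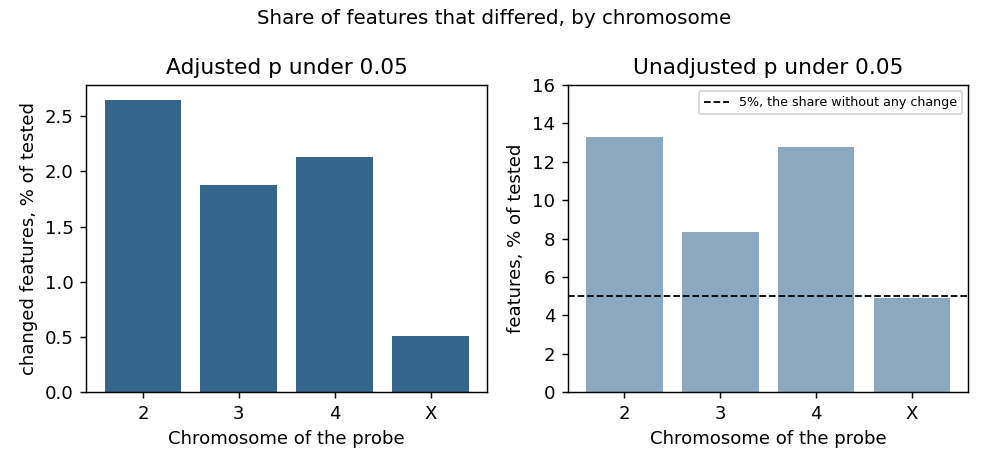
Percent of tested features on each chromosome (horizontal axis) that changed at an adjusted p under 0.05 (left) or had an unadjusted p under 0.05 (right), DIP2 knockdown against control (n = 4 per group). The dashed line marks 5%, the share given by chance; the bar for the X, at 4.88%, is the only 1 of the 4 that lies under it.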

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

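Among 262 groups of 4 arrays examined, over array measures, named genes and list means, 17 had 1 array far from the other 3 by the Dixon ratio (its gap to the nearest array over the whole range), where chance gives about 13.1. Of the tests weighed here, those of chance and of chromosome 3 were planned, and those of list calls, of other probes of a gene, of the X chromosome and of the neighbours of gkt were chosen after the result was seen.

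DIP2 in knockdown replicate 2 stood at -1.35, above the other 3 knockdown arrays at -1.75 to -1.73 (ratio 0.965), and still below every control. Control replicate 3 had 263 outlier-flagged spots against 43 to 50 on the other controls (ratio 0.968). The rank correlation of the deposited table with the median spot signal was 0.9971 on knockdown replicate 3 against 0.9977 on the others (ratio 0.917). Control replicate 1 stood apart for disco (ratio 0.922), CheB53a (0.858), CG9287 (0.885), Fatp1 (0.843) and RpS5b (0.952), and control replicate 2 for RpS15 (0.860). Control replicate 4 had the lowest lncRNA:roX1 signal of the controls, -1.26 against 0.05 to 0.14 (ratio 0.933), and with it the lowest mean of the sex-biased list (ratio 0.852). Knockdown replicate 4 stood apart for CG3397 (0.832), agt (0.860), Ercc1 (0.869) and the axon guidance list (0.877), knockdown replicate 1 for Claspin (0.898) and knockdown replicate 2 for the ecdysone list (0.855).

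The 5 list calls are not beyond chance, since 23 of the 35 splits of the arrays into 4 and 4 called as many lists and the highest of the others called 12.

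For the 306 changed features, only 1 of the 35 splits, the real one, gave as many. The highest of the others gave 49, and the split by slide gave 0. Chance is argued against but not excluded, since 35 splits allow only a coarse test and did not keep the slides balanced. The other splits also mix the groups, which raises their spread, and no split separates group from position on the slide. A difference confined to chromosome 3 is argued against by the upper bound of its odds ratio, 1.22. Sequence variants under a probe may account for part of the list: in 101 genes with a called probe and another over 60 nt away, the other probe moved by a median of 0.33 of the change (95% interval 0.20 to 0.59), which leaves that open. In 44 of them the share was under 0.25 or of opposite sign, as for Fdh, and in 42 it was at least 0.5, as for gkt. The called probes were picked for their change, which lowers the share at other probes even without variants. The share therefore cannot decide this question. A response to DIP2 knockdown stays open for the changed genes, untested apart from the fall of DIP2 itself.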

How the results depend on the processing

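The slide-only fits, the fit on genes of the gene table and the odds ratio for the X were added after seeing the data. The changed-feature count of 306 was 3 (0 higher) after normexp correction, 158 with no filter on dim probes, 888 with array weights (where control replicate 4 had a weight of 10.4), 197 over genes of the gene table, 172 by an ordinary unadjusted test with a 2-fold threshold and 168 with that test adjusted, 0 on slide 1, 6 on slide 2, and 160 to 257 with 1 array left out. Other planned settings gave 242 to 432, among them 324 by quantile normalization (270 shared with the main list), 251 on the deposited values (192 shared), 263 with the slide block (246 shared) and 291 by median centring (166 higher, 125 lower). DIP2 and gkt kept their direction throughout. DIP2 was -0.89 and gkt -1.17 after normexp, without passing, -0.70 and -1.58 on slide 1 and -1.04 and -1.23 on slide 2, where neither passed; with 1 array left out DIP2 ran from -0.97 to -0.80. Whether replicate numbers pair the arrays stays open. The correlations of deviations were 0.24, -0.39, 0.15 and 0.28 for numbers 1 to 4. For number 4 each array was the closest partner of the other, and for number 2 neither was. With the replicate block, 106 features passed (100 shared), DIP2 was -0.87 without passing (adjusted p = 0.108) and 9 lists passed. List calls numbered 3 with quantile normalization, 3 on the deposited values, 9 on slide 1, 3 on slide 2, 0 with an estimated correlation, 1 by fry, and 2 to 6 with 1 array left out. The chromosome 3 odds ratio was 0.77 on the deposited values and 0.84 with array weights, both past the threshold. Normexp turned the sign of CheB53a (-0.64), CG9287 (-0.69), Cyp4ac2 (-0.99), Nepl8 (-0.79), CheB53b (-1.0025), CG33654 (-0.85), Best2 (-0.69), CecA1 (-0.062), Fancl (-0.45) and the list medians of cell cycle (-0.34), cuticle (-0.81), lipid metabolism (0.0028), ribosomal proteins (0.074) and respiration (0.11). It moved the median change of all features from -0.03 to -0.34 and the median SE from 0.13 to 0.27. With normexp the lists of lipid metabolism, ribosomal proteins and respiration passed at these turned medians (camera adjusted p of up to 0.00361). The cuticle median was -0.076 with no filter and -0.069 with array weights. The pan-neuronal median was 0.069 with array weights, where that list passed (camera adjusted p = 0.0260). With the brightest probe COX4 was -0.058 and the list of DIP2 and partners 0.00035. The cause of these shifts was not tested. Of 39 called named genes, 26 passed with every array left out in turn, 3 after normexp, 31 on the deposited values, 28 with no filter on dim probes and 26 with the replicate block. Signal over background limits genes dim in 1 group.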

Other observations

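Tests in this part were chosen after the results were seen. Some transcripts without a gene name also changed, and those given here were picked after their values were seen. TC219002, with a probe on chromosome 4 at 492489 to 492548 of Dm3, was not well above background on any control array and was at least 56.8-fold higher in knockdown brains, at -0.69 ± 0.09 (SD, n = 4, adjusted p = 1.87e-06). TC215719 was at least 9.78-fold higher. The adjusted p of TC219002 belongs to its limma change and does not test the bound. On the deposited processed values TC219002 rose by 1.93 (adjusted p = 9.87e-08) and TC215719 by 0.47 (adjusted p = 0.00463). After normexp correction they were at 2.03 and -0.09, and neither call was kept (adjusted p = 0.355 and 0.926). Spindly, a mitotic dynein adaptor gene, rose by 0.87 (SE 0.09, adjusted p = 0.00285), by 0.34 on the deposited values (adjusted p = 0.0226), and was at -0.19 after normexp correction (adjusted p = 0.769).

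Changed features were sparse on the X chromosome. The odds ratio for the X against chromosomes 2 and 3 was 0.23 (95% interval 0.12 to 0.39, Fisher's exact test, p = 2.20e-11), and an unadjusted p under 0.05 was seen for 4.88% of features on the X, 13.3% on chromosome 2 and 8.36% on chromosome 3. Dimmer or less variable X features are argued against, since 10000 draws of autosomal features matched on level and spread held at least 38 changed features against 14 on the X. At an unadjusted p under 0.05 the odds ratio for the X was 0.43 (95% interval 0.36 to 0.52). Point estimates within slide 1 and slide 2 were 0.48 and 0.80. These ratios repeat the same sparseness at a looser cut, so they cannot tell explanations apart. A candidate explanation is that the groups shared their X chromosomes, where the written genotype places the driver and dicer2, and differed in autosomal background. It was proposed after the result was seen and was not tested. Under this hypothesis many autosomal changes may belong to the strains rather than to DIP2, which these data do not separate, and w, on the X, may reflect a marker copy on the added transgene, which was not tested.

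The fall of gkt sat among other changed genes. Within 500 kb of gkt on 2L there were 8 other changed loci (features merged within 5 kb), against a median of 2 over autosomal features, and 98.8% of autosomal features had fewer. They moved both ways: TC208830 fell by 1.86, while CG17264 rose by 0.80 (-0.89 and 0.45 on the deposited values, both called). NTPase and Spindly were also called on the deposited values, but Fign and tim were not (adjusted p = 0.0948 and 0.601). With no filter on dim probes the calls of tim and NTPase were lost (adjusted p = 0.0961 and 0.0997). The count of changed neighbours was not repeated under these settings. It took no account of how many features were tested in each window, and nearby features share windows. Since gkt was itself picked as changed and was set against all autosomal features, the 98.8% describes its surroundings and is not a test. The changed neighbours leave a chromosome segment around gkt that differs between the groups as a candidate cause of part of its fall. This is stated as a hypothesis. A response of gkt to DIP2 knockdown stays open as well, since no sample here separates the hairpin from the chromosomes it came with.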
